A study of Mus musculus with 16 samples.

How the data were processed

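Long non-coding RNA levels were measured by RNA sequencing in the livers of 16 C57BL/6J mice, with 1 library per mouse and 4 mice in each of 4 groups. The groups received ordinary feed, high-fat feed, high-fat feed with resveratrol at 100 mg/kg per day, or high-fat feed with metformin at 200 mg/kg per day. Per the labels, both drugs were given by gavage. The labels give the age as postnatal day 21, and do not say whether tissue was collected or feeding began at that age. Per the labels' protocols, total RNA was extracted with Trizol and sequenced on an Illumina NovaSeq. Replicates were numbered in the order of the samples, since the labels give no replicate numbers, and the labels name no batch, cage, litter or sex. The titles of the 4 high-fat samples share 1 prefix, while those of each other group carry more than 1, and its meaning is not given in the sources used here. If it marks a cage or litter, that cannot be told apart from the high-fat group in any comparison with it.

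The values are FPKM (reads scaled by transcript length and by the library's total), computed by the authors for each listed transcript and deposited as 1 file per library. Bowtie 0.12.2, Cufflinks 2.1.1 and the GRCm38 genome were used, per the submitters' processing notes. Annotation release, strand handling and filters are not given in the sources used here. All 16 files list the same 51024 transcripts, of which 44554 carry NONCODE IDs, 6326 Ensembl IDs and 144 IDs of assembled transcripts. Protein-coding genes are not among them. Each value times the transcript's length was a whole multiple of 1 step per library in at least 99.997% of values, within a tolerance of 0.05 of a read. That step gave the library totals and the reads per transcript.

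Of the 6326 Ensembl transcripts, 6306 matched GENCODE M21 by ID, and 6243 of these (99.0%) had identical coordinates. FPKM values were summed over the transcripts of each of 5270 Ensembl genes, while other transcripts were kept as they are. This gave 49988 features, and 7413 with an FPKM of at least 1 in at least 4 libraries were tested. NONCODE transcripts made up 6393 of the tested features, Ensembl genes 899 and assembled transcripts 121. Each feature was placed against the coding genes of GENCODE M21 by position alone. It was called exonic with at least 50% of its length in exons, partly exonic with less, and intronic or intergenic with none. Multi-part transcripts whose interval overlaps a gene at any point, and whose inner exons the files do not give, were called spanning. The word does not mean that they cover the gene. Most tested features, 5689 (76.7%), were listed with a length equal to their interval. Because strand was not used, reads of a feature and of an overlapping gene cannot be told apart. A gene symbol given with a feature therefore names its position, not the coding gene's level.

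Differences were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1) values in 1 fit of all 16 libraries with 12 residual degrees of freedom. Benjamini-Hochberg adjustment was made over the 7413 features, and a feature was called with an adjusted p under 0.05. Log2 fold changes and their standard errors (SE) are on that scale. Means and standard deviations (SD) are on the FPKM scale with n = 4 libraries per group. The 6 comparisons were high fat with ordinary feed, each drug with high fat alone, the drugs with each other, and each drug group with ordinary feed. Library measures were compared by two-sided exact permutation tests, for which 4 libraries against 4 allow no p below 0.0286. Shares of called features between places were compared by Fisher's exact test. Features are not independent replicates. Limma p-values of features and permutation p-values of library measures reflect only the spread between these libraries. Fisher's exact p-values count features as units and do not measure that spread.

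The comparisons, the test, the filter, 40 gene lists, 25 key genes and most alternatives were fixed before the data were examined. Those lists held mainly coding genes, so a linking rule was added once the files were seen to hold long non-coding transcripts, before any list result was computed. A feature was linked to a gene when it was exonic, partly exonic or intronic in it, or intergenic within 5 kb, or when it was the listed RNA itself. The feature with the highest mean FPKM stood for its gene, and 19 of the 40 lists had at least 3 linked features and were tested. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all from limma. Fry asks whether a list moves on balance in 1 direction and does not compare it with other features.

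Features to be named were chosen by a rule. For each of the 3 main comparisons these were up to 8 called features with the highest and up to 8 with the lowest log2 fold change. Their 4 values in 1 group had to lie above the 4 in the other, with a mean FPKM of at least 1 in the higher group. The other comparisons used up to 3 in each direction, or those with the smallest p where none passed. Up to 4 members of each list with the smallest p, and the features linked to key genes, were added whatever their result. Of the 25 key genes, 10 had a linked feature, and 15 had none, such as Srebf1, Pparg, Cd36, Plin2, Fgf21, Tnf and Col1a1. Runs of neighbouring features, features with on and off states, shares by place and the clock score were examined only after their values had been seen. A change of sign in a value that was called under neither setting was not counted as a reversal.

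Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, a fit of 2 groups at a time, library weights, a robust variance prior and no variance trend. Single transcripts were also tested, and each library was left out in turn. Added after the data were seen were limma's voom on recovered reads, merged overlapping loci, a covariate for reads of the ribosomal RNA locus, library totals without 7SL and ribosomal reads, and median-ratio scaling without the fourth high-fat library. The fit was tested on simulated data with independent normal noise around the means of the 7413 features, using their fitted spreads. In each of 20 runs, 200 features were changed in the high-fat comparison. The fit called 25.1% of features changed by 0.5 on the log2 scale, 75.1% at 1 and 95.1% at 2, and 4.58% of its calls were false. These rates hold for such noise alone. No outlying library, difference of scale, on and off states or correlation between features was simulated. Tables and figures were made with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.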

Results

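Liver RNA from 16 C57BL/6J mice was profiled for long non-coding transcripts, with 4 mice each on ordinary feed, high-fat feed, high-fat feed with resveratrol and high-fat feed with metformin. Resveratrol is a plant polyphenol and metformin a drug that lowers blood glucose. The libraries held 17.2 to 31.1 M reads (M for mega, mean 22.4 M). Between 3.03 and 6.26 M of these, 15.7% to 23.6% of a library, fell on the listed transcripts. Mean library totals were 21.0 ± 3.49 M reads for ordinary feed, 24.6 ± 4.33 for high fat, 22.2 ± 1.48 with resveratrol and 21.6 ± 2.71 with metformin (SD, n = 4 each). At a length of 1 kb, 1 read corresponded to between 0.0321 and 0.0580 FPKM, so the reads behind a value of 1 FPKM depended on the library and on the transcript's length. Of the 7413 features tested, 2822 (38.1%) lay in introns of coding genes, 1606 (21.7%) were intergenic and 1140 (15.4%) exonic. Another 1127 (15.2%) were spanning, with an interval that overlaps a gene, and 718 (9.69%) were partly exonic.

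A few abundant RNAs took most reads on the listed transcripts. The 7SL RNA, the RNA of the signal recognition particle, took 53.8 ± 3.14% of them in high-fat livers and 45.5 ± 2.81% with ordinary feed (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible; 0.257 after adjustment over 36 tests). Its share was 50.6 ± 2.33% with resveratrol and 52.0 ± 2.33% with metformin. The fourth high-fat library stood apart. There, the ribosomal RNA locus on chromosome 17 (39842995 to 39848829, GRCm38) took 22.6% of listed reads, against 8.80% to 16.1% in the other 15 libraries. Its median ratio to the geometric-mean library was 0.691, against 0.885 to 1.145 elsewhere, and 4274 features reached 1 FPKM, against 5149 to 6492. Its Pearson correlation across features with other high-fat libraries was 0.776 to 0.822, against 0.851 to 0.894 in the other 21 pairs within groups.

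**Figure D1:**
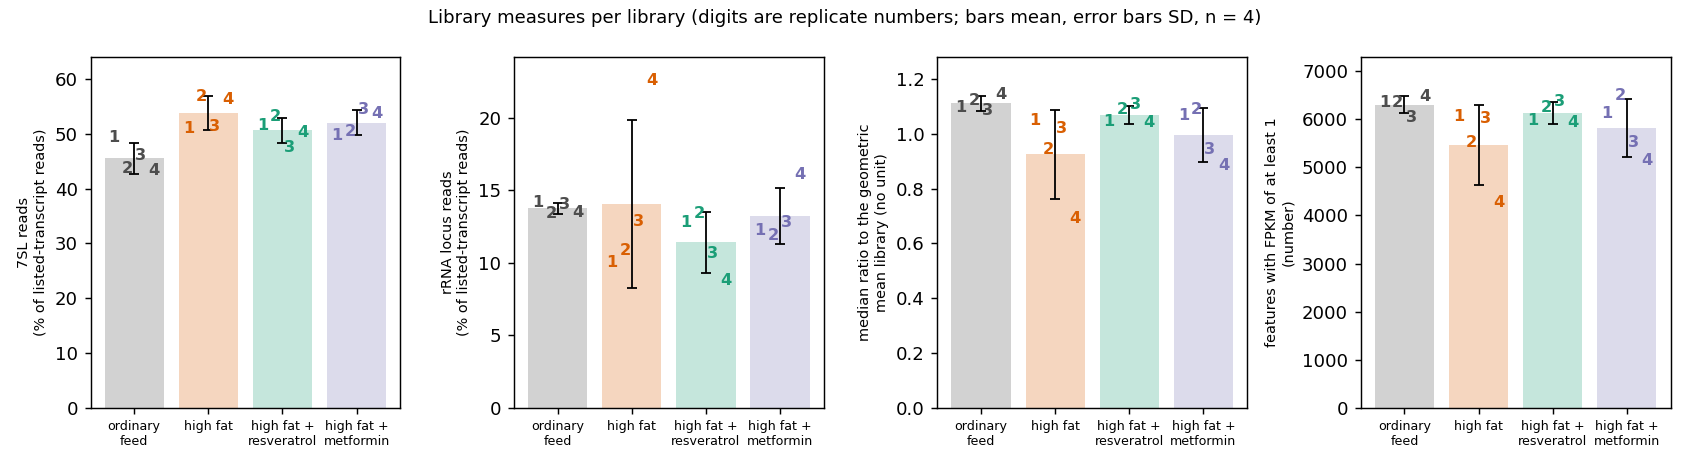
Bars show group means and error bars the SD (n = 4 libraries) of the 7SL share of listed-transcript reads (%), the ribosomal RNA locus share (%), the median ratio to the geometric-mean library (no unit) and the number of features with an FPKM of at least 1; digits are replicate numbers. The fourth high-fat library has the highest ribosomal share (22.6%), the lowest median ratio (0.691) and the fewest features (4274).

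The comparison of high fat with ordinary feed asked what the diet changed in the liver. Features in the 3′ UTRs of Stard4 and Dgat2 were higher on high-fat feed, and features beside Pck1 and within Igfbp2 were lower. The 3′ UTR feature of Stard4 (NONMMUT031869.2), a cholesterol carrier protein, rose from 8.35 ± 1.45 to 22.1 ± 3.65 FPKM (log2 change 1.31, SE 0.21, n = 4 per group, limma adjusted p = 0.00301). That of Dgat2 (NONMMUT062889.2), which makes triglycerides, rose from 112 ± 7.34 to 199 ± 19.7 FPKM (0.82, SE 0.18, limma adjusted p = 0.0124). A feature 4.67 kb upstream of Pck1 (NONMMUT041547.2, chromosome 2, 173142376 to 173148383), the key enzyme of glucose synthesis, fell from 3.15 ± 0.899 to 0.662 ± 0.170 FPKM (-1.30, SE 0.14, limma adjusted p = 0.000238). The intronic feature of Igfbp2 (NONMMUT001470.2, chromosome 1, 72832881 to 72834402), a binding protein of insulin-like growth factors, fell from 15.5 ± 3.79 to 2.09 ± 1.28 FPKM (-2.47, SE 0.37, limma adjusted p = 0.00247).

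Among other called features with high changes were a pair at Egfr and a pair at Aacs. At Egfr, the receptor of epidermal growth factor, a partly exonic feature (NONMMUT008655.2, chromosome 11, 16752342 to 16755821) rose from 11.9 ± 4.92 to 79.2 ± 32.2 FPKM (2.61, SE 0.59, limma adjusted p = 0.0138). An intronic feature of Egfr (NONMMUT008656.2, 16758310 to 16762518) rose from 10.4 ± 4.43 to 49.2 ± 13.5 FPKM (2.16, SE 0.58, limma adjusted p = 0.0269), a call that was lost without ordinary-feed library 1, 2 or 3 or high-fat library 2, 3 or 4. At Aacs, which activates acetoacetate for lipid synthesis, the spanning feature (NONMMUT119417.1, chromosome 5, 125488135 to 125490031) rose from 0.151 ± 0.212 to 3.39 ± 1.55 FPKM (1.87, SE 0.33, limma adjusted p = 0.00437). The feature 4.06 kb downstream (NONMMUT149179.1) rose by 1.77 (SE 0.27, limma adjusted p = 0.00254). An intergenic feature on chromosome 1 (NONMMUT003114.2, 151138185 to 151143841) rose from 2.33 ± 0.530 to 20.4 ± 9.65 FPKM (2.58, SE 0.35, limma adjusted p = 0.00105). The remaining high ones were the spanning feature of Zc3h7a (MSTRG.16066.11; 2.49, SE 0.53), the 5′ UTR feature of Nrep (NONMMUT031874.2; 1.85, SE 0.29) and a pair downstream of Stk19 (NONMMUT029339.2 and NONMMUT029338.2; 1.87, SE 0.42, and 1.85, SE 0.34). Merged with its overlapping transcripts, the Zc3h7a locus changed by 0.83 with a limma adjusted p of 0.199.

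Among features that fell, Gm15441 (chromosome 3, 96555765 to 96566801), which spans Txnip, a gene that responds to glucose, went from 24.2 ± 13.3 to 3.38 ± 1.26 FPKM (-2.30, SE 0.47, limma adjusted p = 0.00926). A multi-part feature overlapping Hdc (NONMMUT146430.1, chromosome 2, 126591782 to 126595454), the histamine-forming enzyme, went from 18.4 ± 5.49 to 4.13 ± 1.62 FPKM (-1.94, SE 0.25, limma adjusted p = 0.00101). A feature 4.47 kb upstream of Acnat1 (NONMMUT047231.2, chromosome 4, 49478386 to 49481012) went from 12.4 ± 1.86 to 2.41 ± 0.701 FPKM (-1.98, SE 0.23, limma adjusted p = 0.000464). A feature 5.58 kb downstream of H2-Q10 (NONMMUT029447.2) changed by -2.24 (SE 0.46), one 4.08 kb upstream of Dhx40 (NONMMUT011310.2) by -3.34 (SE 0.76) and the 3′ UTR feature of Map4k4 (NONMMUT000701.2) by -1.92 (SE 0.33). The 3′ UTR feature of Mis12 (NONMMUT010559.2, chromosome 11, 71025492 to 71027369), a kinetochore gene, went from 5.80 ± 1.45 to 0.158 ± 0.0394 FPKM (-2.53, SE 0.26, limma adjusted p = 0.000171). It took only off and on levels, at most 0.211 in the 4 high-fat libraries and at least 2.45 in the other 12, with nothing between. The 3′ UTR feature of Agfg1 (NONMMUT001706.2) was on in the 4 ordinary-feed libraries alone, at 2.76 ± 0.538 FPKM against 0.0739 ± 0.0342 on high fat (-1.80, SE 0.12, limma adjusted p = 1.78e-06).

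**Figure D2:**
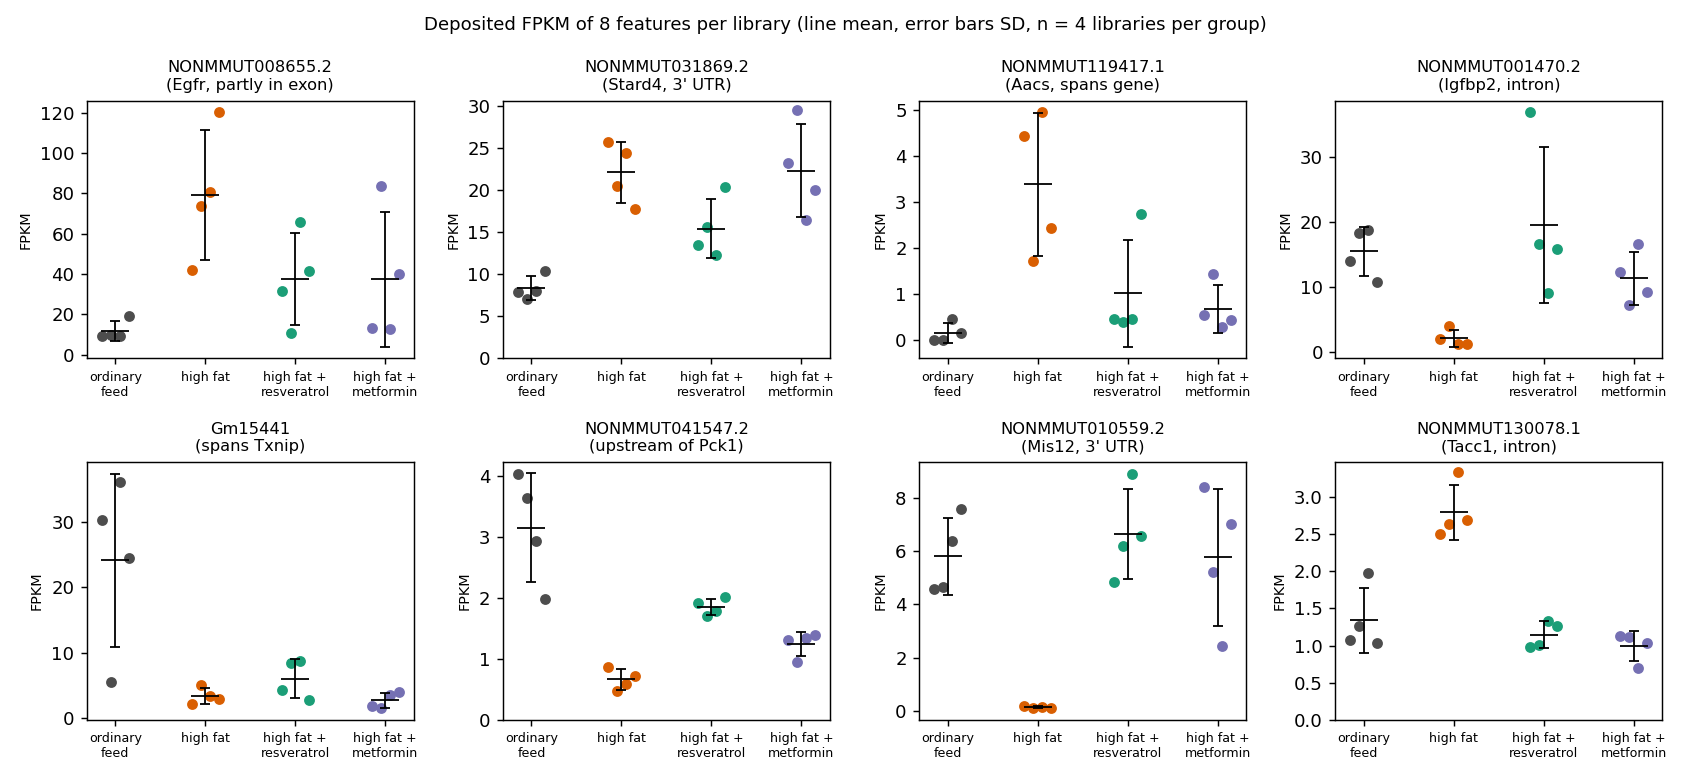
FPKM of 8 features in each of 16 libraries, by group, with the feature and its position above each panel; points are libraries, horizontal lines group means and error bars the SD (n = 4). The intronic Igfbp2 feature averages 15.5 on ordinary feed, 2.09 on high fat and 19.6 with resveratrol, and the Mis12 3′ UTR feature stays at 0.158 on high fat against 5.80, 6.63 and 5.77 in the other groups.

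In all, 1085 of 7413 features were called between high fat and ordinary feed, 210 higher and 875 lower (80.6% lower). With a change of at least 1 on the log2 scale, 69 were higher and 122 lower. Values of the groups did not overlap for 923 of the called features and for 20.9% of all tested features. Chance gives 2.857% where all libraries share 1 scale. Here the median ratios themselves did not overlap, at 1.083 to 1.145 with ordinary feed and 0.691 to 1.048 with high fat. A difference of scale can therefore raise the share, and no share after scaling is given. The split between higher and lower moved with scaling: median-ratio scaling called 813 features, 447 higher and 366 lower (45.0% lower), of which 575 were among the 1085. The median change of all features was -0.16 as deposited and 0.00 with that scaling. The count was 539 without ordinary-feed library 2, 576 without ordinary-feed library 3, 722 without high-fat library 2 and 605 without high-fat library 4.

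Of 12 linked lipogenesis features, 2 rose (Aacs and Dgat2), none fell and 10 did not pass, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.0966). The features of Fasn (0.73, SE 0.50), Scd1 (-0.08, SE 0.63) and Acaca (0.23, SE 0.17) did not pass. Of 5 linked cholesterol synthesis features, Stard4 rose and 4 did not pass; adjusted over the list alone the count was again 1 (camera adjusted p = 0.0966). Without high-fat library 4, where it had 0.0641 FPKM against 20.6 to 23.9 in the other 3, the Sc5d feature of this list went from -0.37, not called, to a called 0.74 (limma adjusted p = 0.00705). With median-ratio scaling without that library camera called the list (adjusted p = 0.0143; adjusted p = 0.288 with an estimated correlation). Among the fatty acid oxidation features that did not pass were those of Cpt1a, which admits fatty acids to mitochondria (-0.67, SE 0.22, limma adjusted p = 0.0557), and Ppara (0.27, SE 0.21). Of 4 gluconeogenesis features, those of Pck1 and Gpt (-0.62, SE 0.17) fell, the same count as adjusted over the list alone. Fry gave the list an adjusted p of 0.00145 downward and camera 0.446. Of 10 features of nuclear respiratory-chain genes, 4 fell (Sdha -0.58, Atp5c1 -0.60, Atp5l -0.49 and Sdhc -0.45), and 7 adjusted over the list alone. Fry gave 0.00145 downward and camera 0.0971. Fry was run on the deposited values alone, where the median of all features was -0.16. A downward fry value can hold that shift in part, for any list. Under median-ratio scaling or quantile normalization the Sdhc, Atp5l and Gpt calls were lost. The Atp5c1 and Sdha calls were lost without ordinary-feed library 2 or high-fat library 4, Atp5c1 also without ordinary-feed library 3 or high-fat library 2. The Gpt call was lost without ordinary-feed library 1 or 2 or high-fat library 3 or 4, and Atp5l without ordinary-feed library 1 or 2 or high-fat library 2 or 3.

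Of 8 features of clock genes, Per3 (1.16, SE 0.28) and Tef (0.75, SE 0.19) rose, while Clock (-0.82, SE 0.18) and Tsc22d3 (-1.45, SE 0.44) fell; adjusted over the list alone 3 rose and 4 fell (camera adjusted p = 0.446). The Tsc22d3 call was lost without ordinary-feed library 2, 3 or 4 or high-fat library 2, 3 or 4, that of Tef without ordinary-feed library 1, 2 or 3 or high-fat library 4, and that of Per3 without ordinary-feed library 2. The merged locus of Tef changed by -0.26 (limma adjusted p = 0.302). Of 4 periportal features, those of Pck1 and Cyp2f2 (-0.65, SE 0.20) fell, also when adjusted over the list alone (camera adjusted p = 0.0971; fry 0.000665). Of 9 insulin and glycogen features only Igfbp2 fell, against 2 adjusted over the list alone. Catalase (Cat, -0.57, SE 0.14) was the 1 of 7 antioxidant features to fall, as when adjusted over the list alone. Canx (-0.66, SE 0.21) was the 1 of 6 features of the endoplasmic reticulum stress list to fall, as when adjusted over the list alone. The Cat call was lost without ordinary-feed library 1, the Canx call without any 1 of the 8 libraries, and the Cyp2f2 call without any 1 of ordinary-feed libraries 2, 3 and 4 and high-fat libraries 2, 3 and 4. Gm15441 was the 1 of 10 lncRNAs listed for obesity to fall, with 1 higher and 1 lower adjusted over the list alone. Of 6 ribosomal-protein features, that of Rps18 fell (-0.47, SE 0.11) and the 7SL gene Rn7s1, linked through Rps29, rose (0.50, SE 0.13). The Rn7s1 call was lost without ordinary-feed library 2, 3 or 4 or high-fat library 2 or 4, without a filter, with 2 groups fitted at a time and with median-ratio scaling without high-fat library 4, and under quantile normalization, which sets the change of the most abundant feature to 0. Under median-ratio scaling or quantile normalization the Tsc22d3, Cyp2f2, Cat, Canx and Rps18 calls were lost, and with 2 groups fitted at a time those of Cat, Atp5l, Atp5c1, Tef, Tsc22d3 and Cyp2f2. Without a filter the calls of both Egfr features, NONMMUT029339.2 and the Dhx40 feature were lost, as were those of the list members named as called, except Stard4, Aacs, Pck1, Igfbp2 and Gm15441.

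The 6 major urinary protein (Mup) features were the list that camera called, with a median change of 0.63 (camera adjusted p = 0.0145; adjusted p = 0.428 with an estimated correlation). With median-ratio scaling camera did not call it (adjusted p = 0.151). With that scaling and without high-fat library 4 camera called it upward (adjusted p = 0.0143, and 0.288 with an estimated correlation). No Mup feature passed by itself, 3 rose adjusted over the list alone, and their near-identical copies make each value uncertain. No feature passed among 10 of the energy-sensing and sirtuin list, 5 male-biased, 4 bile acid, 4 xenobiotic, 3 interferon and 3 stellate features. Adjusted over the list alone, 1 energy-sensing feature rose and 1 fell, and 2 male-biased features rose and 1 fell; 3 of the 5 male-biased features (Mup1, Mup11 and Mup12) are also in the Mup list. Prkaa2, a subunit of AMP-activated kinase, had 0.60 (SE 0.20, limma adjusted p = 0.0536), and Cyp7a1, the first enzyme of bile acid synthesis, -0.30 (SE 0.36). The 3′ UTR feature of Sirt1 (NONMMUT005901.2), the deacetylase studied with resveratrol, had -1.47 (SE 0.59, limma adjusted p = 0.1003). It was off, at most 0.0883 FPKM, in 5 libraries and at least 2.91 in the other 11. The 3′ UTR feature of Gsr (NONMMUT065156.2) was off in 7 libraries from all 4 groups.

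Called features were spread unevenly over kinds of position. Of 2822 intronic features 464 fell (16.4%; odds ratio against all others 2.00, Fisher's exact p = 1.22e-21), while of 946 features in 3′ UTRs 30 fell (3.17%; odds ratio 0.218, Fisher's exact p = 1.37e-23). Intergenic features rose most often, with 88 of 1606 (5.48%; odds ratio 2.70, Fisher's exact p = 2.17e-11). The shares higher were 1.59% for introns and 0.846% for 3′ UTRs, and 9.84% of intergenic features fell. With median-ratio scaling 6.91% of introns were lower and 4.68% higher, 1.16% of 3′ UTR features lower and 3.28% higher, so that their balance turned, and 4.73% of intergenic features lower and 9.15% higher. Without high-fat library 4 these were 8.26% and 1.35%, 1.16% and 1.59%, and 4.17% and 5.04%. Neighbouring features also moved together, so Fisher's exact p-values, which count each feature as independent, cannot be taken at face value. Runs of such features were sought after the values had been seen. With at most 20 kb between neighbouring tested features, called or not, and at least 6 called in a run, 10 runs held 128 called features. The longest lay beside Eipr1 on chromosome 12 (28898573 to 29189242), where 52 of 88 features fell (median of the 88, -0.85), against 23 with median-ratio scaling (median -0.71) and 9 without high-fat library 4 (median -0.78). Both ends of this run are those of NONMMUT141350.1, which was not called (0.29, limma adjusted p = 0.502). Of 25 features around Foxa2, a liver transcription factor, on chromosome 2 (147936506 to 148040248), 12 rose (median 1.02), and 11 did so without high-fat library 4 (median 1.14). Of 13 between Ctcfl and Pck1 (173110818 to 173148687), 9 fell (median -1.03), and 8 without that library (median -1.03). Of 16 at Tacc1 on chromosome 8 (25208103 to 25256612), 7 rose (median 0.59), and 2 without that library (median 0.49). With median-ratio scaling and without that library, 2 features fell at Eipr1 (median -0.69) and 7 between Ctcfl and Pck1. In that setting 14 rose around Foxa2 and 5 at Tacc1.

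**Figure D3:**
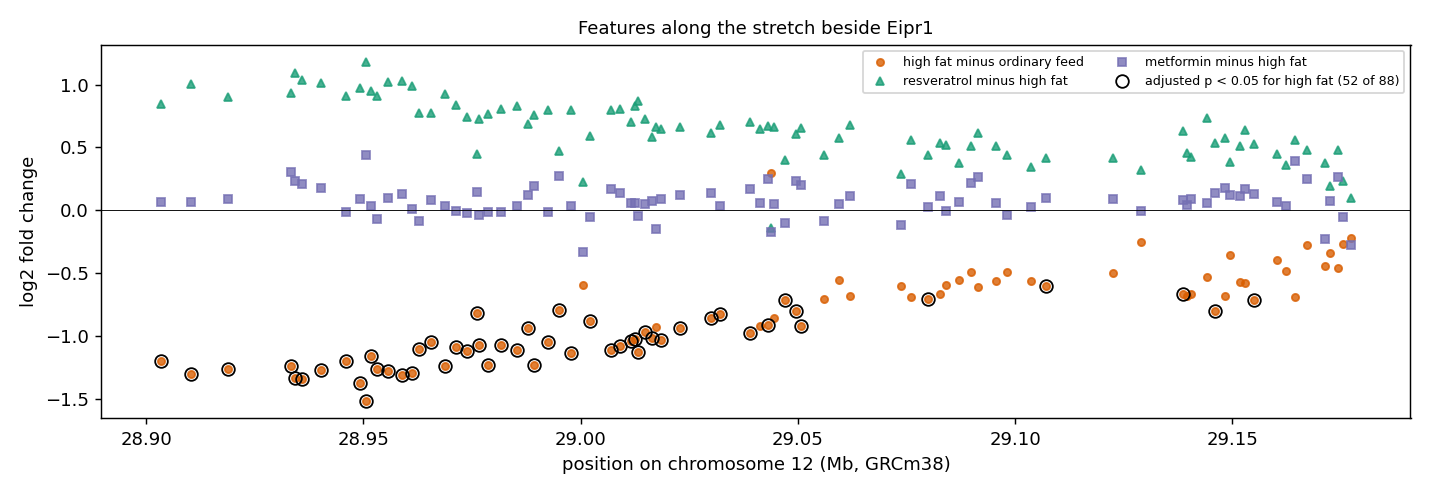
Log2 fold changes of the 88 tested features along chromosome 12 beside Eipr1 (x axis, position in Mb on GRCm38), for high fat minus ordinary feed (circles), resveratrol minus high fat (triangles) and metformin minus high fat (squares), with rings on the 52 called for high fat. The medians were -0.85, 0.65 and 0.07; the median for high fat was -0.71 with median-ratio scaling and stayed negative.

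The comparison of resveratrol with high-fat feed alone asked which changes the drug made on that diet. The 3′ UTR feature of Mis12 was on in all 4 resveratrol livers, at 6.63 ± 1.68 FPKM against 0.158 ± 0.0394 (2.70, SE 0.26, n = 4 per group, limma adjusted p = 0.000224). The intronic Igfbp2 feature rose to 19.6 ± 12.01 from 2.09 ± 1.28 FPKM (2.65, SE 0.37, limma adjusted p = 0.0139), and the feature upstream of Acnat1 to 8.41 ± 3.05 from 2.41 ± 0.701 (1.43, SE 0.23, limma adjusted p = 0.0314). Intronic features of Gldc, the glycine decarboxylase (NONMMUT034407.2, chromosome 19, 30164751 to 30165769; 0.72, SE 0.12, limma adjusted p = 0.0314), and Sox5 (NONMMUT059409.2; 0.63, SE 0.11, limma adjusted p = 0.0395) also rose. The intronic Tacc1 feature (NONMMUT130078.1, chromosome 8, 25224918 to 25225781) fell from 2.79 ± 0.374 to 1.15 ± 0.176 FPKM (-0.82, SE 0.13, limma adjusted p = 0.0264).

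These 6 features, 5 higher and 1 lower, were the ones called, with 1200 at an unadjusted p under 0.05. The groups did not overlap in 7.93% of all tested features (2.857% by chance where all libraries share 1 scale). The balance turned with scaling: median-ratio scaling and quantile normalization each called 13, with 3 higher and 10 lower. Pck1 (0.79, SE 0.14, limma adjusted p = 0.0515) and Aacs (-1.33, SE 0.27, limma adjusted p = 0.0733) did not pass. Of the 19 lists, insulin and glycogen had 1 call (Igfbp2, also adjusted over the list alone) and the other 18 none. Adjusted over the list alone, 1 lipogenesis feature fell, 1 feature rose in each of gluconeogenesis, bile acid, antioxidant, endoplasmic reticulum stress, male-biased and periportal, and 2 clock features rose and 3 fell. Camera called no list (lowest adjusted p = 0.151). The count moved with single libraries: it was 1 without high-fat library 3 or 4 or resveratrol library 2, 3 without resveratrol library 1, 11 without resveratrol library 3, 16 without high-fat library 1 and 57 without resveratrol library 4. Through the shared spread it was also 2 without ordinary-feed library 2, and 10 and 11 without metformin libraries 1 and 2. Mis12 passed in each of these. The other 5 calls were lost without high-fat library 3 or 4 or resveratrol library 2, those of Acnat1, Gldc, Sox5 and Tacc1 also without resveratrol library 1, Gldc and Sox5 also without high-fat library 2, and Sox5 without resveratrol library 3. With 2 groups fitted at a time or without a filter these 5 calls were lost as well. Those of Gldc and Sox5 were lost under median-ratio scaling and quantile normalization, and that of Sox5 also without a variance trend and with the ribosomal covariate.

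The comparison of metformin with high-fat feed alone asked the same of the second drug. The Mis12 feature was on in all 4 metformin livers (5.77 ± 2.57 FPKM; 2.45, SE 0.26, n = 4 per group, limma adjusted p = 0.000762). The Tacc1 feature fell to 0.998 ± 0.201 from 2.79 ± 0.374 FPKM (-0.93, SE 0.13, limma adjusted p = 0.00959). Igfbp2 (2.02, SE 0.37, limma adjusted p = 0.0767) and Pck1 (0.44, SE 0.14, limma adjusted p = 0.420) did not pass. These 2 features were the ones called, with 554 at an unadjusted p under 0.05 (8 with median-ratio scaling, 1 higher and 7 lower), and none of the 19 lists had a call (lowest camera adjusted p = 0.127). Adjusted over the list alone, 2 cholesterol features rose, 1 rose in each of gluconeogenesis, insulin and periportal, and 1 fell in each of lipogenesis and energy sensing. The count was 1 without high-fat library 3 or metformin library 3, 6 without high-fat library 1, 7 without high-fat library 2, 9 without high-fat library 4 and 3 without metformin library 1, and the Tacc1 call was lost without high-fat library 3 or metformin library 3 and with 2 groups fitted at a time.

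All 6 resveratrol calls and both metformin calls were called for high fat in the opposite direction, and both metformin calls were among the resveratrol calls. Independent lists would share 0.619, 0.146 and 0.000809 features, which leaves the shared high-fat libraries out. In 100 simulated sets with no effect that share them, the overlaps were at most 4, 4 and 6 (means 0.06, 0.04 and 0.08). Such sets hold no feed effect, so they cannot show what sharing gives beside one. With the high-fat libraries split so that none was shared, they were 1 to 7, 0 to 6 and 0 to 1 over 6 divisions. Of the 1085 high-fat features, 96.9% had the opposite sign with resveratrol and 93.4% with metformin. Both comparisons use the same 4 high-fat libraries, which gives opposite signs with no effect at all. Of features called with 2 of the high-fat libraries, 74.2% to 89.9% had the opposite sign with resveratrol and 54.6% to 90.3% with metformin against the other 2. As deposited, the median change of all features was -0.16 for high fat. Against high fat it was 0.13 with resveratrol and 0.07 with metformin. A difference of scale can therefore raise these shares, and no share over all features or after scaling is given. The correlation of fold changes across features was -0.641 for resveratrol (mean of 100 simulated sets with no effect -0.474, range -0.895 to 0.586) and -0.579 for metformin (simulated -0.510, -0.784 to 0.532), each within the simulated range. The covariances were -0.10 (simulated -0.0426, -0.0846 to 0.0164) and -0.0819 (simulated -0.0451, -0.0711 to 0.0175), each beyond it. With the high-fat libraries split so that no library was shared, the mean correlations were -0.273 (simulated -0.433 to 0.428) and -0.195 (simulated -0.437 to 0.433), each within the simulated range. Each simulated set used 1 division, so its range is not that of a mean over 6. The single divisions gave -0.318 to -0.232 and -0.270 to -0.119, also within it. The fold changes of the 2 drugs, both against the same high-fat libraries, correlated at 0.598 (simulated 0.489, -0.604 to 0.771), with a covariance of 0.0666 (simulated 0.0433, -0.0209 to 0.0940), both within the simulated range. With those libraries split, the correlation was 0.0512 to 0.212 over the divisions (simulated -0.476 to 0.332), again within it.

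**Figure D4:**
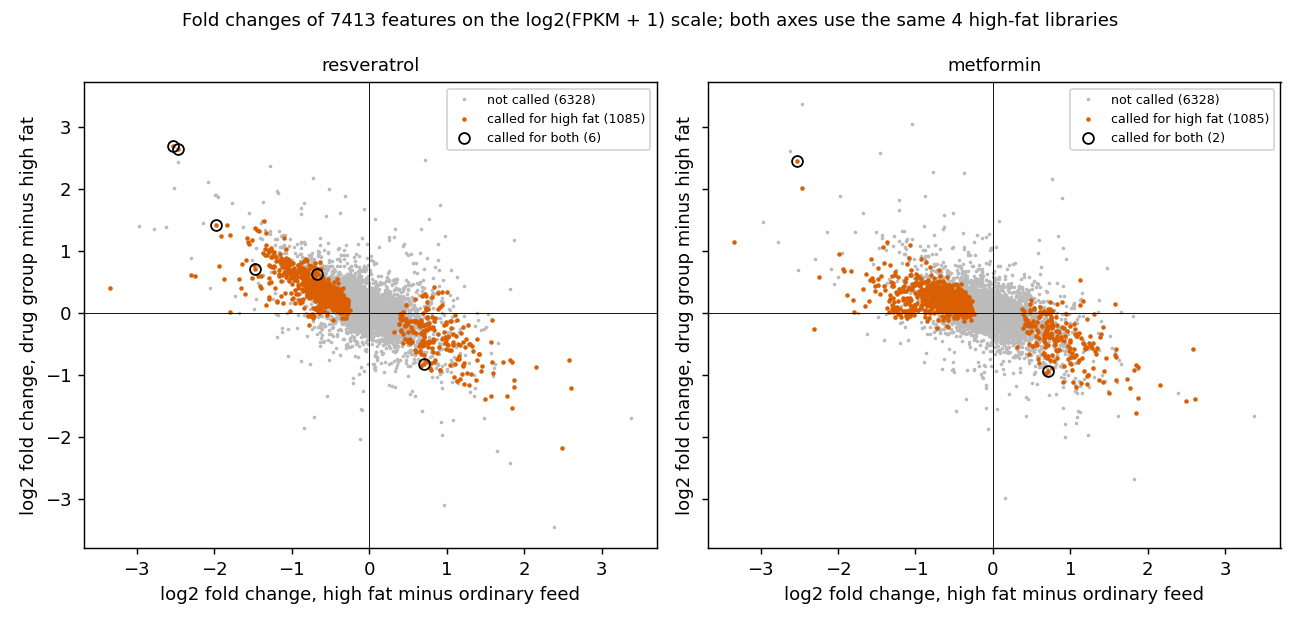
Log2 fold change of 7413 features for high fat minus ordinary feed (x axis) against resveratrol minus high fat and metformin minus high fat (y axes, 1 panel each); orange points are the 1085 called for high fat and rings those called on both axes. Of the orange points 96.9% and 93.4% have opposite signs, and because both axes use the same high-fat libraries, simulated sets with no effect also give a correlation of -0.474 and -0.510.

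The comparison of resveratrol with metformin asked whether the drugs differed on the same diet. Limma called 0 features, with 471 at an unadjusted p under 0.05 and 0 called by limma's voom on recovered reads. The smallest p belonged to the intronic feature of Larp1 (NONMMUT009908.2; 1.36 ± 0.248 FPKM with resveratrol and 3.31 ± 0.236 with metformin; -0.87, SE 0.15, n = 4 per group, limma adjusted p = 0.186). The feature of the imprinted gene Peg3 (NONMMUT059852.2; 1.86, SE 0.46) and the lncRNA AU020206 (-1.45, SE 0.35) both had a limma adjusted p of 0.765. NONMMUT060513.2 (0.53), NONMMUT025542.2 (0.42) and Gm37651 (-0.46) did not pass either. Camera called the list of 5 cholesterol synthesis features, with a median of -0.40 for resveratrol minus metformin (adjusted p = 0.00349; adjusted p = 0.270 with an estimated correlation; fry adjusted p = 0.5085), while 0 of the 5 were called and 1 was lower adjusted over the list alone. By that adjustment 1 clock feature was higher and 1 lower. Without resveratrol library 1, or without high-fat library 1, the count of features was 1.

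The comparison of resveratrol on high-fat feed with ordinary feed asked what still set those livers apart. The Agfg1 3′ UTR feature (chromosome 1, 82896322 to 82901182) was off in the 4 resveratrol livers, at 0.0925 ± 0.0102 FPKM against 2.76 ± 0.538 (-1.77, SE 0.12, n = 4 per group, limma adjusted p = 2.17e-06). An assembled feature 5.16 kb upstream of Cyp2c29 (MSTRG.21777.1, chromosome 19, 39262434 to 39264250) rose to 13.1 ± 3.43 from 0.628 ± 0.750 FPKM (3.20, SE 0.59, limma adjusted p = 0.0377), and Mup-ps14 by 1.48 (SE 0.27); both belong to families of near-identical copies and are uncertain. NONMMUT003114.2 rose by 1.83 (SE 0.35), and the spanning features of Camk2b (MSTRG.5260.1; -2.39, SE 0.41) and Prkd3 (NONMMUT101464.1; -1.02, SE 0.17) fell. Of 21 called features 11 were higher and 10 lower, with 979 at an unadjusted p under 0.05, and 17 of them were called for high fat with the same sign. Both comparisons use the same ordinary-feed libraries: independent lists would share 1.492 features and simulated sets with no effect at most 1, and with those libraries split the overlap was 1 to 2. The simulated sets hold no feed effect, so they cannot show what sharing libraries gives when the feed has one. No list member was called. Adjusted over the list alone, 3 Mup and 3 male-biased features and 1 cholesterol feature rose. By the same adjustment 3 respiratory-chain, 2 gluconeogenesis, 1 periportal, 1 ribosomal and 1 obesity-listed features fell. Camera called Mup (median 0.96; adjusted p = 2.41e-05), male-biased (0.92; 8.91e-05) and cholesterol (0.57; 0.0213) up, and respiratory chain (-0.33; 0.00186) and periportal (-0.49; 0.0153) down. The Mup and male-biased lists are not separate evidence, since 3 features of near-identical copies are in both. With an estimated correlation, cholesterol had an adjusted p = 0.285 and the other 4 lists an adjusted p = 0.110. The count was 5, 7 and 2 without ordinary-feed libraries 1, 2 and 3, and 2, 9, 10 and 1 without resveratrol libraries 1, 2, 3 and 4, as well as 38 without high-fat library 4 and 12 without metformin library 4. Agfg1 passed in each, while the other 5 named calls were lost in 6 to 8 of the 8 leave-outs and without a filter. Voom did not call the Cyp2c29, Mup-ps14 and Prkd3 features.

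The comparison of metformin on high-fat feed with ordinary feed asked the same of metformin. The Agfg1 feature was again off, at 0.0932 ± 0.0328 FPKM (-1.77, SE 0.12, n = 4 per group, limma adjusted p = 2.18e-06). Stard4 was again higher, at 22.3 ± 5.54 against 8.35 ± 1.45 FPKM (1.30, SE 0.21, limma adjusted p = 0.0191), and Gm15441 at Txnip again lower, at 2.70 ± 1.18 against 24.2 ± 13.3 (-2.56, SE 0.47, limma adjusted p = 0.0444). NONMMUT003114.2 (2.00, SE 0.35) and the spanning feature of Hnf4a, a liver transcription factor (MSTRG.25288.3; 1.73, SE 0.34), were higher. NONMMUT008193.2 upstream of Olfr9 was lower (-1.54, SE 0.30), though its merged locus had -0.22 (limma adjusted p = 0.761). Of 22 called features 7 were higher and 15 lower, with 1488 at an unadjusted p under 0.05, and 20 were called for high fat with the same sign (1.969 for independent lists, at most 2 in simulated sets with no effect, and 2 to 5 with the ordinary-feed libraries split). Here too, sets without a feed effect cannot show what sharing libraries gives beside one. Of 5 cholesterol features 1 rose, and 3 adjusted over the list alone (camera adjusted p = 3.61e-05; adjusted p = 0.109 with an estimated correlation). Camera also called Mup (0.000567) and male-biased (0.00764) up, which share 3 features, and periportal (0.0107) and respiratory chain (0.0375) down. With an estimated correlation Mup and periportal had an adjusted p = 0.149 and the others an adjusted p = 0.244. Called members were 1 lower in each of periportal and gluconeogenesis (Pck1 in both), clock (Clock) and the obesity list (Gm15441). Adjusted over the list alone, 3 periportal and 3 respiratory-chain features fell, 1 fell in each of gluconeogenesis, energy sensing, xenobiotic and the obesity list, 2 Mup and 3 male-biased features and 1 lipogenesis feature rose, and 3 clock features rose and 2 fell. The count was 4, 5 and 49 without ordinary-feed libraries 2, 3 and 4, and 4, 2 and 3 without metformin libraries 1, 2 and 4. Agfg1 passed in each, while the other 5 named calls were lost in 5 to 7 of the 8 leave-outs and without a filter. With 2 groups fitted at a time the Stard4, Gm15441, Hnf4a and Olfr9 calls were lost, and voom did not call the last 3. Libraries outside the pair of groups also moved the count through the shared spread, to 260 without high-fat library 4, 154 without resveratrol library 4, 11 and 9 without high-fat libraries 2 and 3, and 8 and 9 without resveratrol libraries 1 and 3.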

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

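The tests of the patterns weighed here, and the counts over other splits of the libraries, were chosen after the results had been seen. The search for single libraries far from their group was planned: 200 groups of 4 libraries were searched (28 of library measures, 172 of the values of 43 features), and 15 had a library far from the other 3, where chance gives 1 in 20 groups.

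Most features called for high-fat feed were lower, 875 of 1085, and the median of all features was -0.16. Reads of 7SL and the ribosomal RNA locus lowering all other values are argued against as the whole cause: with library totals that leave those reads out, the median was -0.1363. The fourth high-fat library alone stays open: without it 69.8% of called features were lower and the median was -0.089, and without 1 more library of the pair these were 52.0% to 71.3% and -0.065 to -0.107. The scale itself stays open too: median-ratio scaling sets the median near 0 and gave 45.0% lower, and without spiked-in RNA the values cannot tell a broad loss of these transcripts from a rise in other RNA such as coding mRNA, which is not analysed here. The feed may lower these RNAs broadly, which stays untested.

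High-fat changes lay back toward ordinary feed with both drugs, but each such comparison shares the 4 high-fat libraries. With these split so that none was shared, the mean covariance of fold changes was -0.05453 for resveratrol, against -0.0473 to 0.0552 in simulated sets with no effect, and -0.03642 for metformin, against -0.0480 to 0.0424. The mean resveratrol value lay outside that range by less than the spread between the divisions of the libraries. The weakest resveratrol division (-0.04814) lay just outside it too, while the mean metformin value lay within it. Sharing does not enter these split values, but noise between libraries does, and the divisions reuse the same 4 high-fat libraries. Each simulated set used 1 division, so its range is not that of a mean over 6. Only single divisions compare with that range, and those of resveratrol all lay outside it, the weakest just. These values therefore do not settle whether such noise or an effect of either drug moved the features as a whole. Both drugs may partly restore these levels, which is a hypothesis.

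Features in 3′ untranslated exons were on in some libraries and off in others: 218 features had a gap of at least 8-fold (after adding 0.1) with at least 2 libraries on each side, and 136 of them (62.4%) lay in 3′ UTRs, against 12.8% of tested features (odds ratio 13.1, Fisher's exact p = 5.67e-69). A change in the host gene's own RNA is argued against for 19 of the 24 features with a tested exonic neighbour. Their neighbours were higher by at most 0.463 on the log2 scale where the feature was on, against steps of at least 3.69. These 19 were set apart by how far their neighbours lay below the step, so a small difference follows in part from that choice. Such a change cannot be told apart for the features of Maf, Ppm1l, Eif4g2, Purb and Mcmbp. Their neighbours were higher by 0.82 to 2.99, which leaves open a part of steps of 4.06 to 6.00. On and off states placed at random over the libraries are argued against for Mis12 and Agfg1, the 2 features that followed whole groups: high-fat library 4 had 131 of the 218 features off, against 65 to 92 elsewhere, and with these numbers kept 0.103 were found on average in 2000 random placements (permutation p = 0.005 for as many). Reads given to the coding transcript in some libraries may account for the rest, with a share of 62.4% in 3′ UTRs, but coding values are not in the files, so this cannot be told apart from other causes, nor can cage or litter from the feed and drugs for Mis12 and Agfg1, or for any comparison with high fat if the shared title prefix of that group marks one. Without the 218 features the counts were 1082 for high fat, 5 for resveratrol, 1 for metformin, 20 and 21 for the drug groups against ordinary feed, and 0 between the drugs.

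Other splits of the same 8 libraries were fitted for each comparison, 35 in all with the real one. The real split called the most features for high fat (1085, against at most 4 in another split) and for resveratrol (6 against 2). It also did so for resveratrol and metformin against ordinary feed (21 against 2 and 22 against 2). In each of these, 1 of 35 splits was as large, the fewest that 35 splits allow, with no adjustment over the 6 comparisons. Mixed splits also add any real difference to the spread, which can lower their counts. The splits therefore do not exclude chance by themselves. For metformin against high fat, 4 of 35 splits called as many as the real 2 features and another split called 10. For resveratrol against metformin the real count is 0, which all 35 splits reach by construction, so the splits decide nothing there, and the highest other count was 2.

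The library total of high-fat library 2 was 31.11 M reads, far above the 21.9 to 22.9 M of the other 3. AU020206 had 0.52 FPKM in resveratrol library 1, against 0 to 0.0145 in the others of the group. MSTRG.16066.11 at Zc3h7a had 7.122 in ordinary-feed library 1 (others 0.668 to 0.851). NONMMUT005901.2 in the 3′ UTR of Sirt1 had 3.595 in high-fat library 1 (0.0559 to 0.0804), 0.08829 in resveratrol library 3 (3.01 to 4.07) and 0.06952 in metformin library 2 (2.95 to 4.12). The Egfr features NONMMUT008655.2 and NONMMUT008656.2 had 19.27 (9.08 to 10.0) and 17.06 (7.67 to 8.79) in ordinary-feed library 4. The features downstream of Stk19, NONMMUT029338.2 and NONMMUT029339.2, had 9.896 (2.63 to 3.08) and 17.3 (3.07 to 3.47) in high-fat library 4. NONMMUT041547.2 upstream of Pck1 had 0.9487 in metformin library 2 (1.32 to 1.38), and NONMMUT059852.2 of Peg3 had 0.07081 in high-fat library 4 (0.113 to 0.117). NONMMUT060513.2 had 0.8292 in ordinary-feed library 2 (0.939 to 0.959) and 0.5365 in metformin library 2 (0.769 to 0.804). NONMMUT119417.1 at Aacs had 2.746 in resveratrol library 4 (0.394 to 0.453).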

How the results depend on the processing

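Voom, merged loci, the ribosomal covariate, totals without 7SL and ribosomal reads, and median-ratio scaling without high-fat library 4 were chosen after the data were seen. The cause of each change was not tested, except where fewer features (929 of 7413 at a mean FPKM of at least 5), more features (49988 without a filter) or fewer libraries enter by construction. Counts are given in the order high fat, resveratrol, metformin, resveratrol against ordinary feed and metformin against ordinary feed, which were 1085, 6, 2, 21 and 22.

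Without a filter they were 274, 2, 4, 2 and 7, with 2 between the drugs. With a mean FPKM of at least 5 high fat had 117, resveratrol 2, metformin 0 and resveratrol against ordinary feed 8. Median-ratio scaling gave 13, 8, 35 and 60 for the last 4, and quantile normalization 721 for high fat, 13 and 7 for the drugs and 60 for metformin against ordinary feed. With 2 groups fitted at a time high fat had 449 and metformin against ordinary feed 12. Library weights gave 38, 9, 85 and 319 for the last 4, and the ribosomal covariate 15, 14, 38 and 224. Totals without 7SL and ribosomal reads gave 13 for resveratrol and 5 for metformin. Against ordinary feed, voom gave 7 and 11, a pseudocount of 0.1 gave 13 and 14, a pseudocount of 0.5 gave 10 for metformin, and merged loci 47 for metformin. Median-ratio scaling without high-fat library 4 gave 531 for high fat, 10 for metformin, and 61 and 175 against ordinary feed.

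Features called for high fat and back with resveratrol (6) were 1 without a filter, 2 with a mean of at least 5 or with 2 groups, 12 with median-ratio scaling, quantile normalization or totals without 7SL and ribosomal reads, 34 with weights and 14 with the covariate. For metformin (2) they were 0, 1, 7, 6, 8, 14 and 5 with a mean of at least 5, 2 groups, median-ratio scaling, quantile normalization, weights, the covariate and the changed totals, and 9 with median-ratio scaling without high-fat library 4. Features called for both drugs (2) were 1 without a filter, 0 with a mean of at least 5, 7 with median-ratio scaling or the covariate, 6 with quantile normalization, and 5 with weights or with median-ratio scaling without high-fat library 4. Lists called for high fat (1) were 0 with an estimated correlation or median-ratio scaling and 3 with fry or with median-ratio scaling without high-fat library 4 (0 of these with an estimated correlation). Of the 24 calls named for their size in the 3 main comparisons, some of them of the same feature, 15 passed without a filter and 12 with a mean of at least 5.

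Leaving out 1 library of the 2 groups compared gave 539 to 1181 for high fat, 1 to 57 for resveratrol, 1 to 9 for metformin, 0 to 1 between the drugs, and 1 to 16 and 2 to 49 against ordinary feed, where leaving out any 1 of the 16 libraries gave 1 to 38 and 2 to 260. It gave 1 to 54 and 1 to 8 for features back with resveratrol and metformin, 1 to 6 for both drugs, and 17 to 24 for the calls named for their size. Of 258 pairs of a named feature and a comparison, 55 were called, 205 kept their side of the threshold in every setting, and over all settings 265 values lost the call, 50 gained it and 2 reversed. The reversed ones were of NONMMUT068756.2 in the 3′ UTR of Sc5d for high fat (-0.37, not called; -0.77 to 0.74 over the leave-outs, highest without high-fat library 4, and 0.88 with median-ratio scaling as well). No paired analysis was possible because the labels give no replicate numbers. The count model was planned only for files that hold counts and was not run, while voom was run on the reads recovered from FPKM. On simulated data with the group size and fitted spreads of these libraries, 25.1% of changes of 0.5 on the log2 scale were called. Read depth was not simulated, nor was another group size.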

Other observations

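The tests of this part, the clock score and the groups of neighbouring features, were chosen after the values had been seen. Beside the runs already described, 13 of 20 features near Ogfrl1 on chromosome 1 (23256286 to 23295392) fell on high-fat feed (median -0.79), 10 with median-ratio scaling (median -0.56) and 8 without high-fat library 4 (median -0.59). All 8 features of Rapgef2 (chromosome 3, from 79252189; median -0.54) and all 8 of Ptprd (chromosome 4, from 76371187; median -0.80), a receptor phosphatase, fell, against 4 and 8 with median-ratio scaling and 5 and 6 without that library. At Rtn3 6 of 6 fell, at Caprin1 6 of 8 and at Arih1 7 of 10, against 5, 3 and 1 with median-ratio scaling and 6, 5 and 1 without high-fat library 4, where the medians were -0.55, -0.84 and -0.31 (-0.67, -0.85 and -0.40 with all libraries). With that scaling and without that library, 4 fell at Ogfrl1, 4 at Rapgef2, 4 at Ptprd, 5 at Rtn3, 2 at Caprin1 and 0 at Arih1. The medians of these runs against ordinary feed stayed negative with resveratrol (-0.16 at Arih1 to -0.40 at Caprin1) and with metformin (-0.30 at Rapgef2 to -0.54 at Ptprd), against the same ordinary-feed libraries by which the runs had been found, and none of their features was called for either drug against high fat.

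Differences between runs, or between the drugs over a run, were not tested. Relative to high fat, the median of the Eipr1 run was 0.65 with resveratrol and 0.07 with metformin, a difference of 0.55 between the drugs with 0 features called by limma. The median of the Tacc1 run was -0.47 and -0.68, and that of the Foxa2 run -0.39 and -0.49. Mean levels of the Eipr1 features were 2.68 ± 0.770 FPKM on ordinary feed, 0.953 ± 0.368 on high fat, 2.25 ± 1.12 with resveratrol and 1.05 ± 0.388 with metformin (SD, n = 4 each). Mean levels of the Foxa2 features were 4.81 ± 1.10, 9.95 ± 1.38, 7.33 ± 1.63 and 6.77 ± 3.74.

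Another clock phase in the high-fat livers is a candidate explanation for the clock gene features. The mean of Per3, Cry2, Tef, Hlf and Usp2 features minus that of Arntl and Clock, each centred over the libraries, was 1.31 higher on the log2 scale with high fat than with ordinary feed (exact permutation p = 0.0571, two-sided; 0.171 adjusted over 6 tests; higher in 3 of 4 libraries than every ordinary-feed library). With metformin it was 1.36 above ordinary feed, with all 4 libraries above (exact permutation p = 0.0286, the smallest possible; 0.171 adjusted), and with resveratrol 0.57 (exact permutation p = 0.314). No difference passed the adjustment, the hour of tissue collection is not given in the sources used here, and a change of phase cannot be told apart from changes of single features.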
